A study of Homo sapiens with 6 samples.

How the data were processed

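The authors deposited a table of normalized values for 6 libraries and a table of statistics for the comparison of TEADi with GFP. RNA was extracted with the RNeasy Plus kit and libraries were made from poly(A) RNA with the TruSeq mRNA kit, per the labels. The authors' processing notes name Trimmomatic 0.36, STAR 2.5.1, Partek 8.0.19.0819 and the build hg19, without the role or order of each, and the quantifier, the annotation release and the use of strand in counting are not given. The deposited values are CPM, read counts per library size, that the authors scaled with TMM factors, a scaling that compares each library with a reference after trimming extreme genes. The scale was read from the values, whose totals differ between libraries as scaled values do. No value is 0. In each library the smallest value is shared by 1850 to 2183 entries and stands in for 0. Between 88.5% and 89.2% of low values lay within 0.1 of a whole multiple of the smallest value, too few to recover whole reads, so no test on counts was made. The ratio of each gene in the deposited statistics was computed by the authors as the mean of TEADi over the mean of GFP. The p-value and the adjusted p (FDR step up) of each gene were made by the authors with a test that the deposited table does not name.

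All 6 library columns were matched by name to the labels, with 0 left over. The table held 19921 entries. The 421 symbols with more than 1 entry (905 entries) were merged by summing values above the library's smallest value and adding that value once, which left 19437 genes. This choice was made after the values were seen. For 418 of these symbols an entry lay on a sequence outside the chromosomes. Coordinates are those of the authors' table in hg19, with the end given as its stop minus 1. The ends of CTGF, KLF4 and HTRA1 are rounded, so that their last digit is not exact.

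Groups, tests, gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. Genes with at least 1 CPM in at least 3 of 6 libraries were tested, 13640 in all. Values were transformed to log2(CPM + 1), and each gene was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend), without covariates. The test was two-sided with Benjamini-Hochberg adjustment over all genes tested, and genes with an adjusted p under 0.05 were called. A change of at least 2-fold means an absolute fitted log2 fold change of at least 1. Fold differences printed for a gene are ratios of mean CPM, whose smallest values stand for no reads, and printed log2 fold changes are fitted values. Library letters recur in both groups, but the labels do not say that a letter marks a shared day or culture. The letters were therefore not used as pairs. Deviations from the group mean, looked at later, had a correlation across genes of 0.08, -0.06 and -0.02 between libraries of the same letter.

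The 22 gene lists were tested with camera in limma at a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. An estimated correlation and fry were the alternatives. Counts of list members use the calls over all genes. Named genes were the TEAD genes, YAP1, WWTR1, CYR61, CTGF, ANKRD1 and KLF4, the 12 largest fitted rises and 12 largest falls among calls with a mean of at least 10 CPM and groups that did not overlap, and up to 4 called members of each list with the smallest p. Other genes, among them the members of a list that went against the rest, GAPDH, LDHA, MDM2, MX1, TGM1, COL1A2, PGK1, ACTG1, COL17A1 and ITGB4, were chosen after their values were seen. The results of some genes that the rule names are not reported. Of 109 named genes, 30 overlap another gene in the table, 15 of them a gene with at least 10% of their level, and their values hold if counting respected strand. Among these 15, IRF9, JUNB, LOX, SLC16A6, ZNF542 and MT-ND4 are reported below without naming the overlap. The self-test added known changes to simulated values of 2 groups of 3 libraries and ran the same code. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.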

Results

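Messenger RNA was sequenced from SCC9 cells, an established human line derived from an oral squamous cell carcinoma. The cells were transduced with an adenovirus carrying green fluorescent protein (GFP, the control) or TEADi, a protein inhibitor of TEAD according to the labels. The multiplicity of infection was 25, and the cells were harvested 48 h later. TEAD1, TEAD2, TEAD3 and TEAD4 are the DNA-binding proteins through which the co-activators YAP1 and TAZ (encoded by WWTR1) act on transcription. The comparison asks which transcripts differ when they are inhibited. Each group had 3 libraries, lettered A, B and C. Beyond transduction in triplicate the labels say nothing of separate cultures, so p-values measure only the spread between these libraries, which may be technical. Values were read counts scaled to library size with TMM factors (CPM), whose total ranged from 827124 to 915558 per library. Divided by each library's smallest value, the totals came to between 9589768 and 15380584, the nearest measure of depth that the values give. The median standard deviation between libraries of a group was 0.11 in GFP and 0.09 in TEADi on the log2 scale.

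With TEADi, 18 of 22 tested YAP and TAZ targets fell and 3 rose, the largest fall being that of ANKRD1, a stress-induced ankyrin repeat protein, whose mean level was 43.9-fold lower than in GFP libraries. CYR61, a secreted matricellular protein, was 6.24-fold lower. Among the largest rises, ANGPTL4, an inhibitor of lipoprotein lipase, was 43.8-fold higher, the secreted protease HTRA1 27.2-fold, the collagen receptor subunit ITGA2 26.7-fold and the EGF receptor ligand AREG 15.6-fold. Most tested genes of DNA replication, mitosis, the actin cytoskeleton and ribosomal proteins were lower, and most of the extracellular matrix and inflammatory cytokine lists and of the mitochondrially encoded genes were higher. These lists and that of YAP and TAZ targets were called by limma camera with a preset correlation but not with an estimated one (Benjamini-Hochberg adjusted p from 0.25 to 0.537). Without GFP library A the median log2 fold change of the mitochondrially encoded genes was 0.30 instead of 0.86.

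The 6 libraries separated by treatment along the first principal component, which held 85.6% of the variance, against 5.56% for the next. Pearson's r across genes, which are not independent replicates, was 0.992 to 0.996 between libraries of a group and 0.948 to 0.956 between groups. Of 13640 genes tested with limma and Benjamini-Hochberg adjustment, 8299 (60.8%) passed the threshold, 3482 higher and 4817 lower in TEADi. A change of at least 2-fold on the log2(CPM + 1) scale was fitted for 1085 of them, 691 higher and 394 lower, a count that rests on the pseudocount (539 with a pseudocount of 5 and 1564 with 0.1). The 3 TEADi values lay wholly above or below the 3 GFP values in 8970 tested genes (65.8%; chance gives 10%). The balance of directions rested on the scaling. With libraries set to equal totals, 4196 genes were called higher and 4126 lower, and with median-ratio factors 4342 and 3959. Thus 50.4% and 52.3% of calls were higher, against 42.0% with the authors' scaling. Quantile normalization kept the majority lower, with 3800 higher and 4545 lower (45.5% higher). On simulated values of 2 groups of 3 libraries, changes of 1.2-fold, 1.5-fold, 2-fold and 4-fold were called in 36.7%, 79.2%, 94% and 100% of the altered genes tested. Of 161 calls 8 were false (4.97%), with 13545 genes tested. The simulation altered only 200 genes, as many up as down, and gave every gene the same spread between libraries (dispersion 0.00215). In the data 60.8% of genes were called, so these shares need not hold there.

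**Figure D1:**
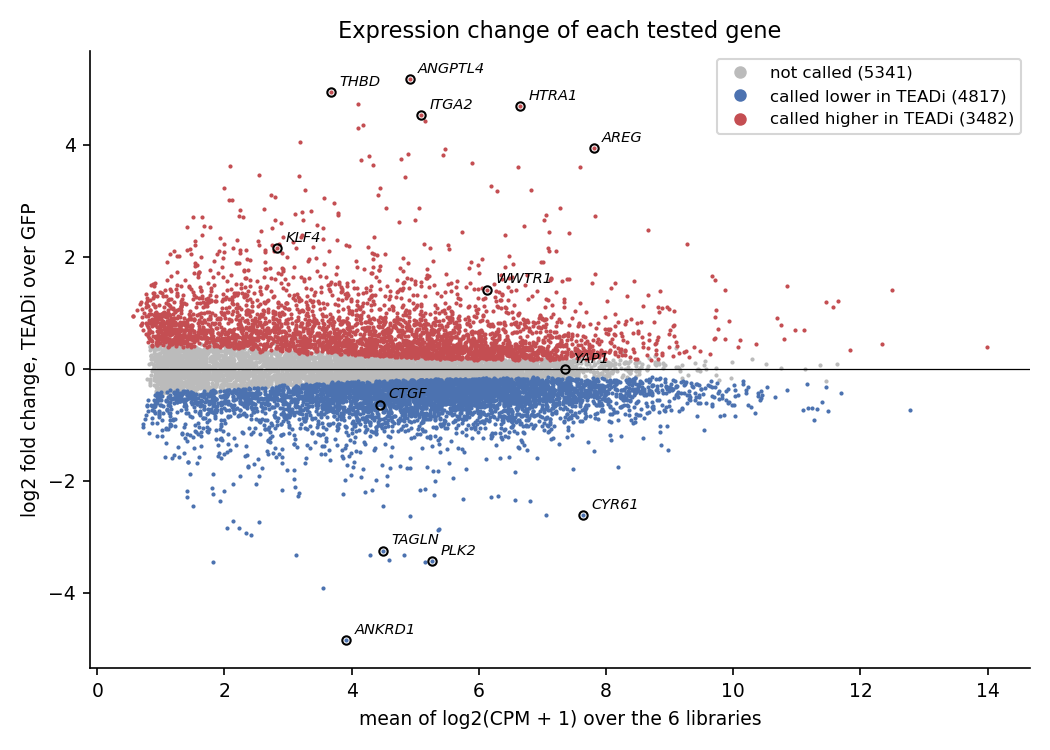
Log2 fold change of TEADi over GFP (vertical axis, from log2(CPM + 1)) against the mean of log2(CPM + 1) over the 6 libraries (horizontal axis) for each of the 13640 tested genes. Red points are the 3482 genes called higher, blue points the 4817 called lower and grey points the rest; ANGPTL4 has the highest labelled value (5.18) and ANKRD1 the lowest (-4.84).

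The 4 TEAD transcripts themselves differed by less than 2-fold. TEAD1 fell from 223 ± 20.3 to 164 ± 9.88 CPM (SD, n = 3 libraries per group here and below), TEAD2 from 15.8 ± 1.39 to 11.2 ± 2.76, and TEAD4 was 1.38-fold lower. TEAD3 went from 30.7 ± 2.41 to 36.9 ± 4.56 CPM, with a Benjamini-Hochberg adjusted p of 0.0281 in limma. The adjusted p of TEAD3 was 0.0789 without GFP library A, 0.0673 without TEADi library B and 0.17 without TEADi library C, within a range of 0.00518 to 0.17 over the alternatives. YAP1 stood at 163 ± 9.38 CPM in GFP and 162 ± 7.31 in TEADi (log2 fold change -0.01; adjusted p = 0.924, limma, Benjamini-Hochberg), and its sign turned with the scaling. WWTR1 rose 2.70-fold, from 42.1 ± 3.67 to 114 ± 7.22 CPM. A gene-level value does not separate reads of a gene from reads of a transduced construct that holds part of it. ANKRD1, on chromosome 10 (hg19, 92671853 to 92681033, minus strand), fell from 80.0 ± 4.38 to 1.82 ± 0.102 CPM, a log2 fold change of -4.84 ± 0.10 (SE; limma, Benjamini-Hochberg adjusted p = 3.5e-16). CYR61, on chromosome 1 (86046444 to 86049645, plus strand), fell from 496 ± 77.8 to 79.5 ± 5.41 CPM (-2.62 ± 0.09; adjusted p = 3.7e-13, limma, Benjamini-Hochberg). CTGF, on chromosome 6 (132269316 to 132272510, minus strand), fell only from 26.5 ± 4.93 to 16.5 ± 1.35 CPM (-0.64 ± 0.12; adjusted p = 2.0e-04, limma, Benjamini-Hochberg). KLF4, a transcription factor of epithelial differentiation on chromosome 9 (110247133 to 110252760, minus strand), rose from 2.36 ± 0.0470 to 14.1 ± 1.47 CPM (2.16 ± 0.13; adjusted p = 2.6e-10, limma, Benjamini-Hochberg).

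**Figure D2:**
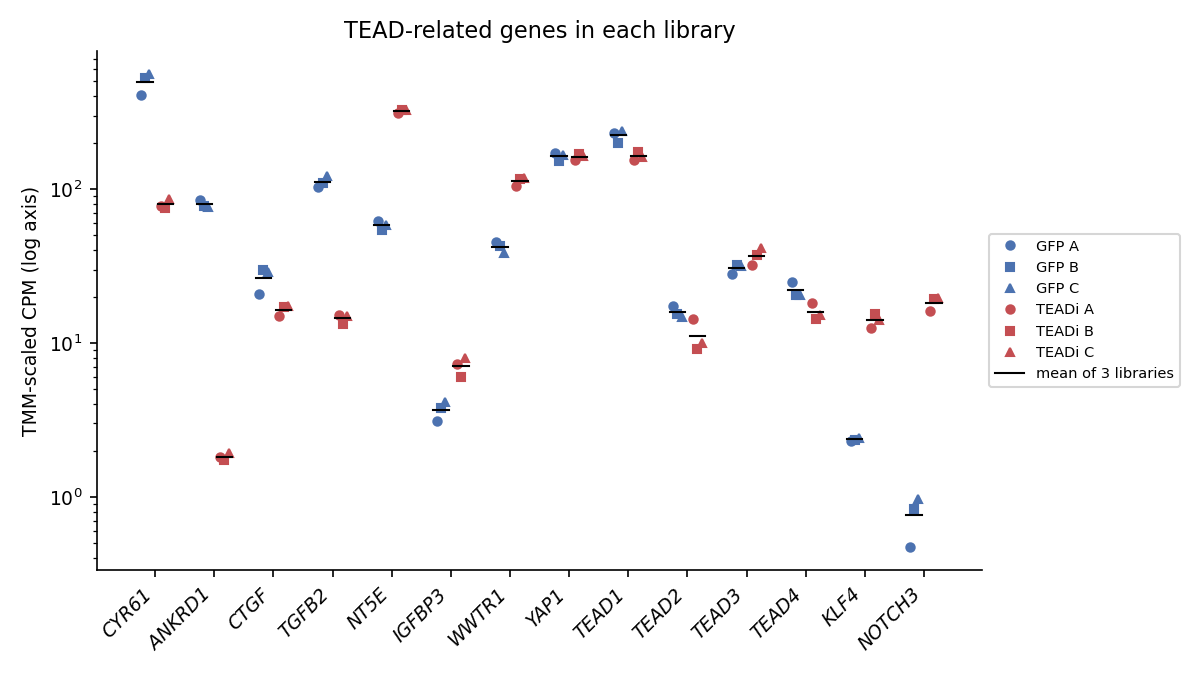
TMM-scaled CPM (vertical log axis) of 14 TEAD-related genes in each library, with GFP libraries in blue, TEADi libraries in red, a marker shape per library letter and a black bar at the mean of 3 libraries. ANKRD1 goes from a mean of 80.0 to 1.82 CPM and CYR61 from 496 to 79.5, while the 6 values of YAP1 lie between 153 and 171 CPM.

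Of 22 tested members of the list of YAP and TAZ targets, 18 fell, 3 rose and 1 was not called, with a median log2 fold change of -0.95. The camera test of limma put the list below other genes (Benjamini-Hochberg adjusted p = 6.9e-06 over 22 lists), and the adjusted p was 0.318 with an estimated correlation. After ANKRD1, the strongest falls among the targets were TGFB2, a TGF-beta ligand (111 ± 10.1 to 14.5 ± 0.954 CPM), and CYR61. The targets that rose, named after their values were seen like the other exceptions given for a list below, were NT5E, the ecto-nucleotidase CD73 (58.3 ± 4.04 to 321 ± 8.21 CPM), the growth factor carrier IGFBP3 and the guanine nucleotide exchange factor DOCK5. Among 25 Hippo pathway components 12 fell and 6 rose, and the list was not called by limma camera (adjusted p = 0.197, Benjamini-Hochberg). FRMD6 (172 ± 10.6 to 34.8 ± 1.07 CPM), WWC1 (3.56-fold lower) and AMOTL2 (154 ± 2.48 to 50.7 ± 4.29), scaffold proteins of the pathway, fell, while WWTR1 rose. Adjusted over the list alone, the counts of 18 lists were those over all genes, and the other 4 are given where they stand.

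By camera with its preset correlation of 0.01, 14 of 22 lists were called, 9 upward and 5 downward. The same test called 6 to 15 lists when the 6 libraries were split so that each side mixed the treatments. In those splits limma called 0 genes, so a list call by this test alone is weak evidence. With a correlation estimated for each list camera called 0, and 3 had an unadjusted p under 0.05, while 19 were called by fry, which asks only whether a list's genes move one way. Apart from the estimated correlation, the 14 lists kept their direction and an adjusted p under 0.05 in every alternative, except the mitochondrial list by fry and the interferon list without GFP library C.

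**Figure D3:**
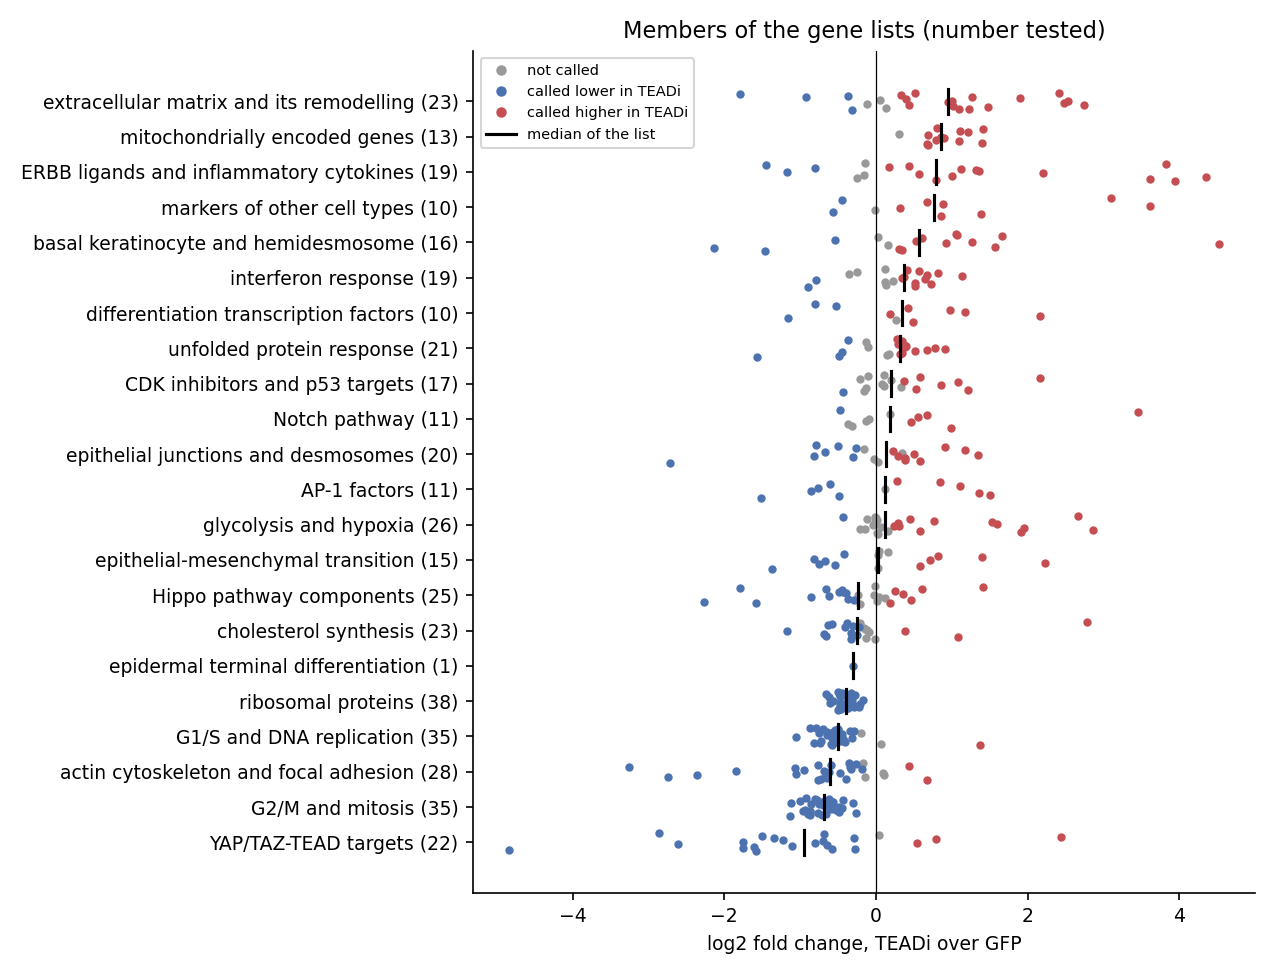
Log2 fold change of TEADi over GFP (horizontal axis) for each tested member of the 22 gene lists, with the number tested in parentheses. Red points were called higher, blue lower and grey not called, and the black bar is the list's median, which runs from -0.95 for YAP and TAZ targets to 0.96 for extracellular matrix genes.

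The falls in growth-related lists were broad and mostly below 2-fold. All 35 genes of G2/M and mitosis fell, with a median of -0.68 (limma camera, Benjamini-Hochberg adjusted p = 1.9e-12; adjusted p = 0.25 with an estimated correlation). ANLN, an actin-binding protein of the cleavage furrow, went from 678 ± 20.1 to 310 ± 10.1 CPM, the transcription factor MYBL2 from 201 ± 13.9 to 91.9 ± 5.80, the kinase PLK1 from 131 ± 2.38 to 65.1 ± 4.56 and the anaphase activator CDC20 from 193 ± 7.48 to 99.1 ± 5.94. Of 35 genes of G1/S and DNA replication, 32 fell, or 33 adjusted over the list alone (median -0.50; limma camera, Benjamini-Hochberg adjusted p = 2.3e-07; adjusted p = 0.344 with an estimated correlation). GINS1, UHRF1 and the origin licensing factor CDC6 led them, with log2 fold changes of -1.06, -0.87 and -0.81. The exception was the G1 cyclin CCND1, which rose from 48.7 ± 5.96 to 128 ± 11.7 CPM and overlaps ORAOV1. All 38 ribosomal protein genes fell (median -0.39; limma camera, Benjamini-Hochberg adjusted p = 2.3e-07; adjusted p = 0.344 with an estimated correlation); with equal totals 35, with median-ratio factors 34 and with quantile normalization 31 were called lower. RPS3 went from 1290 ± 98.7 to 818 ± 15.3 CPM, RPS2 from 1192 ± 85.0 to 777 ± 26.9, RPL5 from 860 ± 37.6 to 565 ± 17.3 and RPL10A from 406 ± 25.6 to 286 ± 10.8. Among 17 CDK inhibitors and p53 targets 7 rose and 1 fell (median 0.20; limma camera, Benjamini-Hochberg adjusted p = 0.0128; adjusted p = 0.344 with an estimated correlation). The oxidoreductase gene TP53I3 rose from 16.8 ± 1.18 to 78.6 ± 1.27 CPM, the CDK inhibitor CDKN1A from 49.6 ± 5.08 to 116 ± 0.913, the kinase PLK3 from 5.85 ± 0.909 to 13.5 ± 1.46 and CDKN1B from 20.3 ± 0.941 to 29.7 ± 2.23. MDM2, a p53 target as well, stood at 109 and 116 CPM and was not called.

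Actin cytoskeleton and focal adhesion genes were lower, with 22 of 28 falling, or 23 adjusted over the list alone, and 2 rising (median -0.60; limma camera, Benjamini-Hochberg adjusted p = 6.1e-06; adjusted p = 0.318 with an estimated correlation). TAGLN, an actin-bundling protein, went from 68.5 ± 4.85 to 6.30 ± 0.191 CPM, but its gene overlaps PCSK7, and strand use in counting is not given. The calponins CNN3 (254 ± 13.1 to 48.5 ± 2.31 CPM) and CNN1 (14.1 ± 1.36 to 1.29 ± 0.520) and the actin-binding protein LIMA1 (179 ± 11.9 to 49.2 ± 1.22) fell as well. Extracellular matrix and remodelling genes went the other way, with 16 of 23 rising and 4 falling (median 0.96; limma camera, Benjamini-Hochberg adjusted p = 6.2e-06; adjusted p = 0.344 with an estimated correlation). The collagen cross-linking enzyme LOX rose from 50.3 ± 3.21 to 342 ± 13.3 CPM, the membrane-bound metalloprotease MMP14 from 171 ± 21.5 to 950 ± 43.3 and the metalloprotease inhibitor TIMP1 from 73.2 ± 2.77 to 396 ± 18.4, and the urokinase receptor PLAUR was 3.91-fold higher. THBS1, SPARC and COL12A1 were among the members that fell. The list of epithelial-mesenchymal transition genes was mixed, 5 of 15 rising and 6 falling (limma camera, Benjamini-Hochberg adjusted p = 0.516). ITGA5, a fibronectin receptor subunit, rose from 287 ± 38.0 to 1348 ± 59.1 CPM and TGFB1 from 46.5 ± 1.58 to 124 ± 10.6, while N-cadherin (CDH2) fell from 167 ± 11.9 to 64.0 ± 2.39 and the repressor SNAI2 from 187 ± 6.29 to 106 ± 4.18. TGFB1 overlaps HNRNPUL1, a more strongly expressed gene.

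Of 16 basal keratinocyte and hemidesmosome genes 11 rose and 3 fell (median 0.57; limma camera, Benjamini-Hochberg adjusted p = 3.1e-04; adjusted p = 0.282 with an estimated correlation). ITGA2 rose from 6.11 ± 0.344 to 163 ± 13.7 CPM, the laminin chain LAMB3 from 44.8 ± 2.05 to 144 ± 7.24 and the hemidesmosomal integrin ITGA6 from 31.6 ± 0.637 to 77.8 ± 1.11, while caveolin (CAV1) fell from 373 ± 11.2 to 135 ± 1.76. The other members called lower, COL17A1 and ITGB4, differed between GFP libraries. COL17A1 stood at 11.9, 9.63 and 1.86 CPM in GFP libraries A, B and C and at 0.776, 0.503 and 0.724 in TEADi. ITGB4 stood at 5.18, 4.17 and 1.65 in GFP and at 1.98, 2.01 and 2.05 in TEADi, so that its lower call rests on GFP libraries A and B. KRT5, a keratin of basal cells that did not reach the filter, showed 21.7, 17.2 and 0.414 CPM in the GFP libraries and at most 0.302 in TEADi. KRT14 and TP63 of the same list did not reach it either. KRT14 stood at 3.57, 1.52 and 0.0690 CPM in GFP and at most 0.121 in TEADi, and TP63 at 0.893, 0.910 and 0.138 and at most 0.0863. The counts and the test of the list leave these genes out. Without GFP libraries A and B, a choice made after seeing the data, GFP library C alone stood against 3 TEADi libraries, so that the spread came from TEADi and the lone library is assumed to vary like them. In that comparison the list kept its direction. The libraries left out were those in which its members COL17A1 and ITGB4 stood high, so the choice itself favours that direction and does not test it. With that single GFP library 6771 genes were called, 1033 of them with at least a 2-fold change. Terminal differentiation could hardly be measured, since of 35 listed epidermal genes 18 were in the table and 1, KRT10, passed the filter. KRT10, which overlaps TMEM99, fell (41.0 ± 3.41 to 33.1 ± 2.17 CPM; limma, Benjamini-Hochberg adjusted p = 0.00526). The list, tested on this 1 gene, was not called (limma camera, Benjamini-Hochberg adjusted p = 0.484). TGM1, a cross-linker of the cornified envelope, lay between 0.357 and 0.910 CPM in all 6 libraries. Differentiation transcription factors rose in 6 and fell in 3 of 10 cases, or 7 and 3 adjusted over the list alone (limma camera, Benjamini-Hochberg adjusted p = 0.134). Beside KLF4, MAF went from 0.416 ± 0.166 to 2.21 ± 0.355 CPM and CEBPB from 85.4 ± 6.54 to 120 ± 7.90, while TFAP2A fell from 46.5 ± 3.07 to 26.1 ± 1.22. In the Notch pathway 5 of 11 members rose and 1 fell (limma camera, Benjamini-Hochberg adjusted p = 0.121). The receptor NOTCH3 rose 24.2-fold, from 0.759 ± 0.253 to 18.3 ± 1.90 CPM, the co-activator MAML2 from 17.3 ± 1.81 to 25.8 ± 1.48 and the target gene HES1 from 0.771 ± 0.276 to 2.53 ± 0.546, while RBPJ, the DNA-binding protein of the pathway, fell from 83.1 ± 6.75 to 59.5 ± 2.34. Junction and desmosome genes split into 9 rising and 7 falling of 20, with a median of 0.13 and a mean of -0.00 (limma camera, Benjamini-Hochberg adjusted p = 0.436). The tight junction protein CLDN1 fell from 10.3 ± 0.341 to 0.728 ± 0.205 CPM and desmoplakin (DSP) from 43.1 ± 4.13 to 24.0 ± 2.43. Envoplakin (EVPL) rose from 8.55 ± 0.541 to 23.4 ± 0.547 and overlaps TEN1-CDK3.

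**Figure D4:**
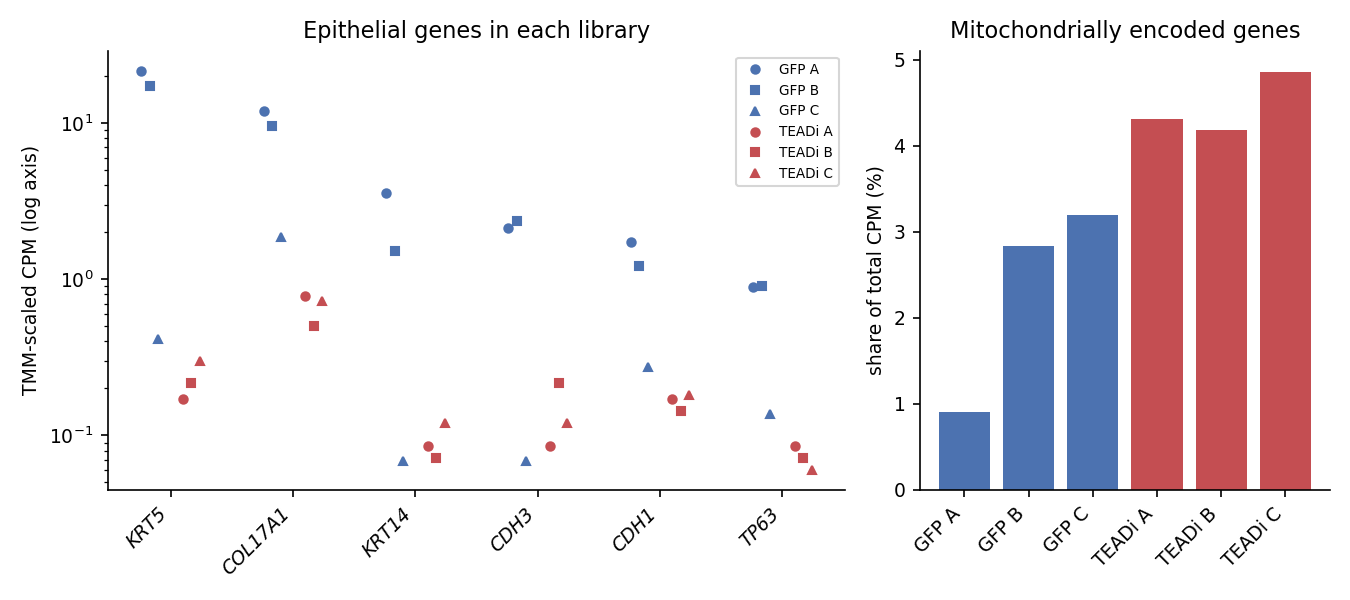
Left, TMM-scaled CPM (vertical log axis) of 6 epithelial genes in each library, GFP in blue and TEADi in red, with a marker shape per library letter; KRT5 stands at 21.7 and 17.2 CPM in GFP libraries A and B and at 0.414 in GFP library C. Right, percent of each library's total CPM that falls on all genes with symbols starting with MT-, more than the listed ones, from 0.898% in GFP library A to 4.86% in TEADi library C.

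ERBB ligands and inflammatory cytokines rose in 13 of 19 cases and fell in 3 (median 0.79; limma camera, Benjamini-Hochberg adjusted p = 2.7e-04; adjusted p = 0.25 with an estimated correlation). AREG rose from 56.0 ± 2.64 to 876 ± 11.1 CPM, the chemokine CCL20 from 27.2 ± 1.42 to 343 ± 13.1, PTGS2, the inducible cyclooxygenase, from 10.5 ± 1.60 to 162 ± 11.7 and CSF3, granulocyte colony-stimulating factor, from 3.09 ± 0.933 to 81.3 ± 7.25. The members that fell were the ERBB ligands NRG1 and HBEGF and the cytokine IL6. The AP-1 factors split evenly, 5 of 11 rising and 5 falling (limma camera, Benjamini-Hochberg adjusted p = 0.684). FOSL1 fell from 251 ± 10.4 to 138 ± 6.52 CPM, JUN from 97.8 ± 2.21 to 57.4 ± 2.70 and ATF3 from 11.2 ± 0.887 to 3.27 ± 0.313, while JUNB rose from 18.0 ± 1.18 to 39.9 ± 2.67. Interferon response genes rose in 11 of 19 cases and fell in 2 (median 0.38; limma camera, Benjamini-Hochberg adjusted p = 0.0115; adjusted p = 0.446 with an estimated correlation). Without GFP library C its adjusted p was 0.0555, and over the alternatives it ranged from 5.0e-04 to 0.446 (limma, Benjamini-Hochberg). IRF9 rose from 8.33 ± 1.32 to 19.5 ± 1.34 CPM, IFI44 1.69-fold and ISG15 from 12.4 ± 1.67 to 20.3 ± 0.615 CPM. MX1, an antiviral GTPase, was not called and stood at 1.96, 2.35 and 0.483 CPM in GFP libraries A, B and C.

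In the list of glycolysis and hypoxia genes 12 of 26 members rose and 1, the glucose transporter SLC2A1, fell (median 0.11; limma camera, Benjamini-Hochberg adjusted p = 3.1e-04; adjusted p = 0.344 with an estimated correlation). The carbonic anhydrase CA9 rose from 56.3 ± 5.00 to 417 ± 18.9 CPM, the angiogenic factor VEGFA from 51.1 ± 6.07 to 328 ± 20.2, the aldolase ALDOC from 29.3 ± 1.08 to 113 ± 5.63 and NDRG1 from 46.1 ± 1.10 to 142 ± 9.45, while the glycolytic enzyme genes GAPDH (2583 and 2689 CPM) and LDHA (2250 and 2232) were not called. CA9 overlaps ARHGEF39, and strand use in counting is not given. Unfolded protein response genes rose in 13 of 21 cases and fell in 4 (median 0.32; limma camera, Benjamini-Hochberg adjusted p = 0.0136; adjusted p = 0.344 with an estimated correlation). EDEM1, which takes part in the degradation of misfolded glycoproteins, rose from 92.4 ± 3.61 to 174 ± 9.45 CPM, the chaperone DNAJC3 from 87.6 ± 2.18 to 141 ± 7.33 and the stress sensor ERN1 from 30.6 ± 3.82 to 53.1 ± 2.38. The members that fell, ASNS (23.9 ± 0.591 to 7.48 ± 1.22 CPM), ATF4, DDIT3 and TRIB3, belong to the ATF4 branch. Cholesterol synthesis genes fell in 13 of 23 cases, or 14 adjusted over the list alone, and rose in 3, and the list was not called (median -0.25; limma camera, Benjamini-Hochberg adjusted p = 0.0628, against 0.0374 without GFP library A and a range of 0.00441 to 0.432 over the alternatives). INSIG1 fell 2.31-fold, HMGCS1 from 95.1 ± 1.69 to 58.9 ± 2.84 CPM and the squalene-forming enzyme FDFT1 from 88.0 ± 4.65 to 55.5 ± 2.55, while TM7SF2 rose from 4.27 ± 0.383 to 35.4 ± 4.35 and overlaps VPS51.

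Mitochondrially encoded genes rose in 12 of 13 cases (median 0.86; limma camera, Benjamini-Hochberg adjusted p = 0.00401; adjusted p = 0.537 with an estimated correlation and 0.199 by fry). MT-CO1, a subunit of cytochrome c oxidase, went from 4155 ± 2347 to 9442 ± 1091 CPM, MT-CO2 from 2323 ± 1164 to 4438 ± 474, MT-ND5 from 667 ± 376 to 1533 ± 147 and MT-ND4 from 2420 ± 1334 to 4888 ± 569. The wide spread in GFP came from library A. There all genes with symbols starting with MT-, more than the listed 13, took 0.898% of the total. Their share was 2.84% and 3.20% in GFP libraries B and C and 4.31%, 4.19% and 4.86% in TEADi. Without GFP library A the median was 0.30. With equal totals 8, with median-ratio factors 8 and with quantile normalization 10 of the 13 were called higher. With robust variances in limma these 4 genes were no longer called (Benjamini-Hochberg adjusted p from 0.11 to 0.148).

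Markers of cell types other than keratinocytes were higher in 7 and lower in 2 of 10 tested cases (median 0.77; limma camera, Benjamini-Hochberg adjusted p = 0.00231; adjusted p = 0.25 with an estimated correlation). The small proteoglycan decorin (DCN) rose 12.4-fold, from 54.5 ± 5.57 to 675 ± 19.4 CPM, lumican (LUM) from 97.2 ± 6.89 to 180 ± 2.75 and the lysosomal protein CD68 from 284 ± 3.13 to 745 ± 36.1. PDGFRA went from 1.26 ± 0.0618 to 18.5 ± 1.84 CPM and overlaps FIP1L1. COL1A1 and the neurofilament gene NEFL fell, and COL1A2, a collagen of the same fibril as COL1A1, stood at 74.5 and 73.4 CPM and was not called.

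The largest fitted rises among genes averaging at least 10 CPM whose groups did not overlap began with ANGPTL4, on chromosome 19 (8428173 to 8439257, plus strand), from 4.12 ± 1.35 to 180 ± 14.0 CPM (log2 fold change 5.18 ± 0.14 SE; adjusted p = 7.3e-15, limma, Benjamini-Hochberg). The ratio of mean CPM was larger for THBD (51.1-fold) than for ANGPTL4 (43.8-fold). Thrombomodulin (THBD), an endothelial anticoagulant receptor, rose from 1.36 ± 0.663 to 69.7 ± 3.78 CPM, and HTRA1, on chromosome 10 (124221041 to 124274420, plus strand), from 18.8 ± 0.894 to 510 ± 10.2 (4.69 ± 0.06; adjusted p = 3.2e-18, limma, Benjamini-Hochberg). The solute carrier SLC16A6, the surface glycoprotein CDCP1, the lysosomal protein LAPTM5, the metalloprotease ADAM8, GFPT2 of hexosamine synthesis and LTBP3, a carrier of latent TGF-beta, completed the 12 with ITGA2, CSF3 and AREG, the smallest log2 fold change being that of LTBP3 (3.84). SLC16A6 was given in 2 entries, whose values were summed. The largest falls after ANKRD1 were the membrane ubiquitin ligase MARCH4 (44.3 ± 3.39 to 2.01 ± 0.211 CPM), TRIM58 (log2 fold change -3.46) and the polo-like kinase PLK2 (126 ± 7.04 to 10.7 ± 1.11). RP1-140K8.5, a transcript named by its clone on chromosome 6 (3905144 to 3912213, minus strand), fell from 77.2 ± 2.40 to 6.37 ± 0.598 CPM, and RP11-346D6.6, on chromosome 10 (54210634 to 54230293, minus strand), from 61.3 ± 1.53 to 5.19 ± 0.493. The annexin ANXA3, the phospholipase PLCB4, TAGLN, SERPINB7, TGFB2 and the zinc finger gene ZNF542 completed the list of 12, the smallest fall being that of ZNF542 (-2.62).

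The authors' deposited table of the same comparison held 19891 entries, of which 8627 had an adjusted p under 0.05, 3755 higher and 4872 lower. Of these, 2396 had a ratio of at least 2-fold, 1557 higher and 839 lower, against 1085 fitted on the log2(CPM + 1) scale. Those 1085 are among 13640 genes that were merged by symbol and passed the filter. The authors' count covers all entries, neither merged nor filtered here, so the scale is not the only difference. The same table gave ANKRD1 a ratio of 0.0228, CYR61 0.160, CTGF 0.621, KLF4 5.95 and WWTR1 2.70 in TEADi over GFP. Among 13260 genes with a single entry in both, the authors' deposited table called 7612 and limma 8069, with 7315 called by both and all of these in the same direction. The log2 ratios of the authors' deposited table and the fitted log2 fold changes had a Pearson's r of 0.965 and a Spearman's rho of 0.995 across genes, which are not independent replicates. The 20 highest and the 20 lowest ratios of the authors' deposited table, which reached 7453 for PGK1 and 3.3e-05 for ACTG1, belonged to symbols listed more than once. After the entries of a symbol were summed, PGK1, a glycolytic kinase, stood at 1123 CPM in GFP and 1528 in TEADi, and ACTG1, cytoplasmic actin, at 3285 and 1997.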

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

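Keeping entries of a symbol apart, leaving out symbols with more than 1 entry and leaving out GFP libraries A and B, which leaves 1 GFP library, were chosen after seeing the data, and the other alternatives were planned. Called genes numbered 7170 to 8049 when 1 library was left out and 8232 with the letter as a replicate block. With a pseudocount of 5, genes with at least a 2-fold change numbered 539 (350 higher, 189 lower), since a larger pseudocount shrinks changes of low values, and 1564 with a pseudocount of 0.1. Over the alternatives, 2039 values of named genes kept direction and side of the threshold and 10 lost the call (6 of TEAD3 and those of MT-ND5, MT-CO1, MT-CO2 and MT-ND4 with robust variances). The other 6 were of YAP1, whose log2 fold change was 0.0714 with equal totals, 0.0910 with median-ratio factors and 0.105 with quantile normalization. Leaving out 1 library it ranged from -0.0551 to 0.0263 and turned positive without GFP library A (0.0247), GFP library C (0.00617) or TEADi library A (0.0263). With an estimated correlation no list was called by limma camera, with Benjamini-Hochberg adjusted p of 0.318 for YAP and TAZ targets, 0.282 for basal keratinocyte genes, 0.344 for G1/S genes and 0.25 for G2/M genes. The cause was not tested. The ERBB ligand and cytokine list and the markers of other cell types lost their calls as well. Their estimated correlations, -0.018 and 0.0046, were below the preset 0.01, so correlated members do not account for the loss in these lists. By fry 6 lists that camera did not call passed, with Benjamini-Hochberg adjusted p (limma) of 0.0294 for the 1 tested gene of terminal differentiation, 0.00555 for Hippo components, 0.0027 for differentiation transcription factors, 0.0022 for the Notch pathway, 0.0331 for epithelial-mesenchymal transition and 0.00441 for cholesterol synthesis, while the mitochondrial list did not pass (0.199). The AP-1 list ranged from 0.658 to 0.968 leaving out 1 library and changed direction without TEADi library A (0.968) or TEADi library C (0.944); the cause was not tested. The planned tests on counts were not run because whole reads could not be recovered. At a depth of 9589768 to 15380584 smallest steps, 36.7% of simulated 1.2-fold changes were called.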

Other observations

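Families of genes whose symbols start with the same letters, and all tests in this part other than the splits of the libraries, were chosen after the results were seen. Among families called by camera, most MRPL, MRPS, TIMM, NUP and EXOSC genes fell, and most HIST, COL and HLA genes rose. Of 48 MRPL genes, which encode proteins of the large mitochondrial ribosomal subunit, 37 fell and 0 rose, with a median log2 fold change of -0.46 (limma camera, Benjamini-Hochberg adjusted p = 7.5e-06 over 150 families; 0.926 with an estimated correlation), and 27 of 30 MRPS genes fell. MRPL37 went from 124 to 52.4 CPM. Of 19 NUP genes, mostly nuclear pore components, 18 fell, NUP107 from 135 to 75.1 CPM, and NUP62CL rose. Of 14 TIMM genes of mitochondrial protein import 13 fell, TIMM10 from 85.9 to 41.1 CPM, as did 8 of 10 EXOSC genes of the RNA exosome. Of 15 tested HIST genes 11 rose, HIST1H2BK from 6.24 to 32.1 CPM, though near-identical copies make their reads hard to assign. Of 23 COL genes 14 rose and 4 fell, with COL6A1 going from 91.9 to 237 CPM and COL6A2 from 87.8 to 207. Of 13 HLA genes 9 rose and 0 fell, HLA-B from 30.1 to 61.4 CPM. These families kept the sign of their medians under equal totals, median-ratio factors and quantile normalization. Camera called 24 of the 150 families, 17 of them lower, fry called 85 and camera with an estimated correlation called 0, with 3 at an unadjusted p under 0.05.

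Of 323 symbols listed more than once with at least 1 CPM in every library, 200 had a different leading entry in different libraries, and in each of these at least 90% of the level lay on 1 entry in every library. The change of leading entry ran inside a group in 192 and along the groups in 8, which is 4% of the 200, near the 3.23% that chance gives with 2 entries. The sum over entries varied with a median standard deviation of 0.10 on the log2 scale, close to the 0.11 of genes with 1 entry, against 2.07 for a single entry. Reads of a gene that were given to one copy of the reference or another, library by library, are a candidate explanation of the extreme deposited ratios of PGK1 and ACTG1. The PGK1 entry with that ratio, on chromosome X, led only in TEADi library B. The ACTG1 entry, on chromosome 17, led only in GFP libraries A and C. An effect of TEADi on the copies would have made most changes follow the groups, and 8 did.

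Of genes in the fixed lists, 12 stood at 0.5 CPM or more in both GFP libraries A and B and at least 4 times above GFP library C, namely KRT5, KRT14, CDH1, CDH3, TP63, COL17A1, ESRP1, GRHL2, JAG2 and the interferon genes BST2, MX1 and OASL, against 1 and 0 for the other pairs of GFP libraries and 0 for pairs of TEADi libraries. Over all genes the same rule gave 34 for this pair, 16 and 27 for the other GFP pairs and 24, 24 and 27 for the TEADi pairs. The median log2 ratio of the 12 genes to the TEADi mean was 3.82 in GFP library A, 3.75 in GFP library B and -0.0788 in GFP library C. The rule that picked the genes holds GFP library C low, so this value says nothing on TEADi lowering these genes, and 5 of the 12 (KRT5, COL17A1, ESRP1, CDH1 and TP63) were above all TEADi libraries in GFP library C as well. That effect stays open. OASL was below the TEADi mean in GFP libraries A and B as well, and the members other than those 5 were below it in GFP library C. ESRP1 and TP63 stood at only 0.138 CPM in GFP library C, against the smallest value, standing for no reads, in every TEADi library. BST2 and GRHL2 were at the smallest value in GFP library C and in every TEADi library. Their ratio, which is also the median of -0.0788, therefore reflects only the size of the smallest values. RNA of another epithelial source in GFP libraries A and B, which would hold the 12 genes at a single ratio between those libraries, could not be told apart from a difference between cultures. The chi-square of that ratio over its degrees of freedom, where counting error alone gives about 1, was 1.25, inside the 0.772 to 2.51 of other sets of genes.

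Mitochondrially encoded genes had a median log2 fold change of 0.86, and of 0.30 without GFP library A, where 12 of 13 still lay higher. The low share in GFP library A may therefore account for the larger part of the rise but not for all of it. A single factor per library for all mitochondrial reads would have left no gene apart from the others. Relative to the mean of the 13 genes the groups did not overlap in 10, 5 higher and 5 lower. Chance gives 10% for a gene taken alone, but the 13 are not independent. The mean is that of the same 13 genes, so relative rises in some force relative falls in others. An effect of TEADi on these transcripts remains open for the rest.

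The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every other split sets 2 libraries of a treatment with 1 of the other. Part of the difference between treatments remains in it, and the rest widens the spread inside its groups, which holds down the number of genes called. Counts of genes from those splits therefore cannot tell whether the real count arose by chance. The real split gave 8299 called genes in limma and the highest other split 0, so that 1 of 10 splits reached the real count. For changes of at least 2-fold the real split gave 1085 and the highest other 0, again 1 of 10. For lists called by camera the real split gave 14 and the other splits 6 to 15, so that 2 of 10 reached it. The other one set GFP libraries A and C with TEADi library B against the rest. The number of lists called therefore does not set the real split apart.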
